A study of Homo sapiens with 5 samples.

How the data were processed

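The series holds 5 SPLIT-seq libraries of IMR-90 fibroblasts. Per the submitters' processing notes, reads were aligned to hg19 and counted with STARsolo; neither the version nor the annotation release was stated. The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization and no cell filter, for 57905 genes and 442368 barcode combinations in each library. All values were whole counts, as checked. A deposited table pairs each barcode of the first round with a condition; these barcodes matched the third part of the cell barcodes, the only part with 48 values. Condition and replicate of each cell were read from that table and from the titles, which the labels call biological replicates.

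Barcodes with at least 1000 UMIs were used as cells, with 500 and 2000 UMIs as alternatives. Wells with no condition in the table were left out, which removed 26493 cells from the time course. Doublets were not called. Cells and wells are not replicates, so counts were summed per condition and biological replicate. The time course had 14 such sums and the single exposure 8. The sums of a condition from both libraries of replicate 2 were added. The double exposure was planned as a comparison with untreated cells, but its table lists none, so peroxide was compared with nutlin-3a and with quiescence as ratios of counts scaled to a common library total (CPM). Choices of tests, filters, gene lists and alternatives were made before the data were examined unless the text says otherwise.

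Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM factors, a design with the biological replicate as a block, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over all tested genes at 0.05. The time course kept 19753 genes with 6 residual degrees of freedom, a biological coefficient of variation of 0.179 and TMM factors of 0.870 to 1.09. The single exposure kept 14256 genes with 3 residual degrees of freedom, a coefficient of 0.125 and factors of 0.926 to 1.14. Log2 fold changes are edgeR estimates with standard errors derived from the test, written as estimate ± standard error, and levels are mean ± SD in CPM. The pairing by replicate number was checked by the correlation of residuals between conditions of the same replicate, which exceeded 0.1 in 19 of 21 condition pairs of the time course (lowest 0.0611) and in 5 of 6 of the single exposure (lowest 0.0893). In the time course a number also marks separate libraries, but in the single exposure all cultures share 1 library, so there the pairing is not established and the block rests on the plan alone. DESeq2 1.42.0 was run with the same design as an alternative.

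The 24 gene lists were written from general knowledge beforehand. They covered p53 targets, secreted factors of senescent cells, nuclear genes known to fall in senescence, cyclin-dependent kinase inhibitors, S phase, G2/M phase, replication histones, homologous recombination, NRF2 antioxidant genes, immediate early genes, heat shock, unfolded protein and ATF4, interferon response, extracellular matrix, contractile genes, cholesterol synthesis, FOXO and quiescence, TGF-beta response, lysosome and autophagy, mitochondrially encoded genes, and markers of epithelial, endothelial, immune and pericyte cells. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. In the double exposure a list's median log2 ratio was placed among 10000 random lists of genes of like expression, drawn within 50 ranks each side, from members with at least 20 summed counts.

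The rule for named genes was fixed beforehand. For replicated comparisons it took the 10 called genes with the largest change each way with a mean of at least 32 CPM and the same direction in every replicate, leaving out clone names and mitochondrially encoded genes, applied in the time course at 4 h and day 7. It added up to 2 called genes with the largest change of each list. Genes always included were, among others, CDKN1A, MDM2, GDF15, CDKN2A, LMNB1, HMGB2, MKI67, TOP2A, IL6, IL8, MMP1, COL1A1 and HMOX1. The double exposure used the 10 largest ratios each way among genes with at least 100 summed counts and 32 CPM in 1 condition. Cell states used the 10 largest changes each way on the held-out counts. The text names part of these and summarises the rest.

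For cell states, 50% of each count was drawn at random (binomial, seed 20) for clustering and the rest was held out for testing. The 2000 most variable genes gave 30 principal components, a graph of 15 nearest neighbours and Leiden clusters at resolution 0.5, with 0.25 and 1 as alternatives (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2; plots with matplotlib 3.10.9). Held-out counts were summed per culture and state with at least 50 cells and tested with edgeR with the replicate as a block. Sums within conditions numbered 64 in the time course (31 residual degrees of freedom) and 12 in the single exposure (5), from 14 and 8 cultures. A state was given a list's name when at least 3 of its 10 leading genes belonged to the list, a count chosen after the data were seen, as were the contrasts of states within a condition. Cycling cells were counted after thinning each cell to 1000 UMIs. Gene neighbours came from GENCODE v29 on GRCh38, matched by Ensembl identifier; of 19922 coding genes 6645 that overlap another were left out. A little-expressed gene had under 5 CPM in untreated cells, and an expressed neighbour at least 32.

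Procedures were tested on data simulated from these samples. With 100 genes changed 2-fold, edgeR recovered 50 at 4 h, 40 on day 7, 70 for peroxide against untreated cells and 70 against nutlin-3a; at 4-fold it recovered 91, 92, 98 and 96. Genes left unchanged were called in 9 of 18645, 7 of 18707, 13 of 13629 and 20 of 13668 cases. For states 4 against 1 of peroxide-treated cells 65 and 97 were recovered at 2-fold and 4-fold, and for states 2 against 1 on day 7, 52 and 96. Camera called 3 of 3 shifted lists at the preset correlation in both experiments and 3 of 3 and 2 of 3 with an estimated one. It called 0 of 17 unshifted lists. Simulated genes were independent, so this cannot show how often either setting errs where genes of a list vary together. Simulated cells of 1 population gave 1 cluster, and of 2 populations 2, with 200 of 200 changed genes called and 12 others. The random-list percentile found 10 of 10 raised lists and 0 of 40 unchanged ones. Its simulated counts held counting error alone and no variation between single cultures. A planted neighbour ratio of 2 came back as 1.86 and one of 1 as 1.10.

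Alternatives were no TMM factors, DESeq2, no low-count filter, other UMI minimums, no replicate block, either library of replicate 2 alone, both of its libraries kept apart with the library as the block, and leaving out each sample in turn. Depth limits what was detectable for genes of low count, and counts of 0 were set at a floor of 3 counts. Cell barcodes under the UMI minimum and unlisted wells were not used here beyond the counts given in the closing part.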

Results

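IMR-90 cells, a line of diploid human lung fibroblasts, were sequenced by SPLIT-seq, in which the RNA of fixed cells receives barcodes in 3 rounds of pooling and splitting. The time course held untreated cells and cells taken 4 h and 1, 2, 3, 4 and 7 days after hydrogen peroxide, each from 2 biological replicates. Replicate 1 was sequenced in 1 library and replicate 2 in a pair of libraries, whose counts were summed as the titles give them 1 number; whether they hold the same cultures is not stated, so n = 2 rests on the titles. The single-exposure experiment held untreated cells, peroxide-treated cells, cells arrested with nutlin-3a (which blocks the p53 ligase MDM2) and cells made quiescent in low serum, with 2 biological replicates of each in 1 library. The double-exposure experiment held 1 culture each of peroxide-treated, nutlin-3a-treated and quiescent cells and no untreated cells, so its values carry no replicate error. The 5 libraries held 208484051, 191944365 and 159570973 counts (time course), 60723631 (single exposure) and 22488405 (double exposure) over all barcodes. Cells with at least 1000 UMIs in wells with a listed condition numbered 72428, of which 50686 belonged to the time course, 18429 to the single exposure and 3313 to the double exposure. Per condition and library, the time course held 551 to 4725 cells and 1212961 to 37934341 counts, with a median of 1892 to 6090 UMIs per cell. In the single exposure each replicate had 1960 to 2581 cells and 3904406 to 7372702 counts, with medians of 1601 to 2638 UMIs. The double exposure gave 782 to 1408 cells per condition, 2199078 to 2801483 counts and medians of 1537.5 to 2302 UMIs. Untreated cells of the first library of replicate 2 stood apart, with 551 cells, a median of 1892 UMIs and 8.51% of their counts on ribosomal RNA genes, against 0.804 to 1.72% in the other conditions of that library. Intervals around cell shares in the text are exact (Clopper-Pearson) 95% intervals and cover counting error only.

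The comparison of cells 4 h after peroxide with untreated cells asked which genes responded first. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 19.1-fold (log2 fold change 4.26 ± 0.36, adjusted p = 3.51e-05). Its level was 153 ± 72.6 against 7.82 ± 4.22 CPM (counts scaled to a common library total, mean ± SD, n = 2). The p53 target CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 4.02-fold (2.01 ± 0.31, adjusted p = 0.00116), and MDM2 rose 3.52-fold (1.81 ± 0.24, adjusted p = 0.000522). The stress cytokine gene GDF15 rose 8.33-fold (3.06 ± 0.43, adjusted p = 0.000701). PTGS2, the gene of the prostaglandin-forming enzyme COX-2, rose 5.68-fold (2.51 ± 0.52, adjusted p = 0.00616), and the hexokinase gene HK2 rose 6.74-fold (2.75 ± 0.29, adjusted p = 0.000141). Proliferation genes had begun to fall, MKI67 to 0.365 and the topoisomerase gene TOP2A to 0.356 of the untreated level (-1.45 ± 0.38, adjusted p = 0.0201 and -1.49 ± 0.35, adjusted p = 0.0108). In all, 3273 of 19753 tested genes were called by edgeR, 1841 higher and 1432 lower, and DESeq2 called 3330. Among called genes with a mean of at least 32 CPM and the same direction in each replicate, those that rose most were LDHC, a testis-type lactate dehydrogenase (6.29, 64.0 ± 63.7 against 0.696 ± 0.658 CPM), HMOX1, C15orf26 (3.39), LINC00536 (3.37), the ciliary rootlet gene CROCC (3.15), WDR74 (2.82), the glutathione transferase gene GSTO2 (2.75), HK2, SPDYA (2.51) and PTGS2. Under the same limits those that fell furthest included PIF1 (-2.44), hsa-mir-6723 (-2.02), GABRB1 (-1.82), BUB1B (-1.79) and CCNF (-1.78). Estimates for CDKN2A (0.26), HMGB2 (-0.49), IL6 (0.78), IL8 (0.94), MMP1 (-0.59) and COL1A1 (-0.34) were not called. Without TMM factors the median log2 fold change of all genes was 0.18 and 81.1% of the calls were higher, against 56.2% with them. Leaving out 1 sample moved the number of calls both ways (range in the closing part). Without the replicate block there were 1385.

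Camera called 12 lists at 4 h at the preset correlation and 0 with an estimated one, and of the 12 the p53, NRF2, ATF4 and FOXO lists had an upward direction. Of 39 measured p53 targets 27 rose and 0 fell (33 and 0 adjusted within the list, median log2 0.97, camera adjusted p = 1.57e-18, 0.421 with an estimated correlation), with BTG2 (3.22) and GDF15 (3.06) highest. Among 27 antioxidant genes under the transcription factor NRF2, 12 rose and 0 fell (14 and 0 adjusted within the list, median log2 0.73, camera adjusted p = 1.7e-07, 0.421 with an estimated correlation), HMOX1 among them. The unfolded-protein and ATF4 list had 23 measured genes, of which 11 rose and 0 fell (14 and 0 adjusted within the list, median log2 1.04, camera adjusted p = 2.77e-07, 0.421 with an estimated correlation), led by the mTOR inhibitor gene DDIT4 (3.74) and SESN2 (2.47). FOXO and quiescence genes went both ways, 6 of 23 up and 2 down (7 and 2 adjusted within the list, median log2 0.32, camera adjusted p = 0.0451, 0.641 with an estimated correlation), SEPP1 (2.70) and FOXO1 (1.73) among those that rose. Of 54 G2/M genes 0 rose and 40 fell (0 and 50 adjusted within the list, median log2 -1.09, camera adjusted p = 8.99e-26, 0.421 with an estimated correlation). Of 42 S-phase genes 4 fell and 1 rose (1 and 3 adjusted within the list, median log2 -0.30, camera adjusted p = 0.00229, 0.675 with an estimated correlation). Homologous recombination genes counted 4 lower of 24 (0 and 4 adjusted within the list, median log2 -0.45, camera adjusted p = 3.45e-05, 0.421 with an estimated correlation), including BRIP1 (-1.07) and BARD1 (-1.04). The nuclear genes known to fall in senescence counted 5 of 14 (0 and 7 adjusted within the list, median log2 -0.57, camera adjusted p = 7.19e-05, 0.421 with an estimated correlation), including the lamin gene LMNB1 (-1.40). Matrix genes fell in 7 of 37 cases (0 and 7 adjusted within the list, median log2 -0.44, camera adjusted p = 0.000653, 0.641 with an estimated correlation). Contractile genes had 1 higher and 3 lower of 26 (0 and 2 adjusted within the list, median log2 -0.33, camera adjusted p = 0.00818, 0.641 with an estimated correlation), SORBS2 (0.97) and FLNA (-0.95) the examples. Replication-dependent histone genes had 1 lower of 22 (0 and 1 adjusted within the list, median log2 -0.74, camera adjusted p = 0.000756, 0.515 with an estimated correlation). Of 15 mitochondrially encoded genes 2, MT-ND6 (-1.89) and MT-ND5 (-1.40), fell (0 and 1 adjusted within the list, median log2 -0.92, camera adjusted p = 0.000817, 0.641 with an estimated correlation). The median mitochondrial share of cells differed between libraries, from 0.138 to 1.49%. Lists not called by camera included the immediate early genes (2 up and 1 down of 23, EGR3 at 2.44 and JUNB at 1.99) and heat shock genes (1 up of 16, HSPA1B at 1.89). Nor were lysosome and autophagy genes (3 up and 1 down of 25) and TGF-beta response genes (3 up of 21) called as lists. Secreted factors of senescent cells had 4 higher and 1 lower of 40, VEGFA (1.91) among the former, with a median of -0.20, a mean of 0.13 and an upward camera direction (adjusted p = 0.664). Cyclin-dependent kinase inhibitors had 2 higher of 7, CDKN1A and CDKN2B (1.80). Cholesterol synthesis had 2 lower of 23, MVK (-1.61) and FDPS (-0.77), and interferon response genes had 0 calls among 20. Marker lists of other cell types had 1 call each for endothelial (VWF, 1.64) and epithelial (KRT19, -1.91) genes and 0 among 8 pericyte genes. The epithelial list had a median of 0.30 and a mean of -0.40, and too few members of the immune list were counted for a test.

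**Figure D1:**
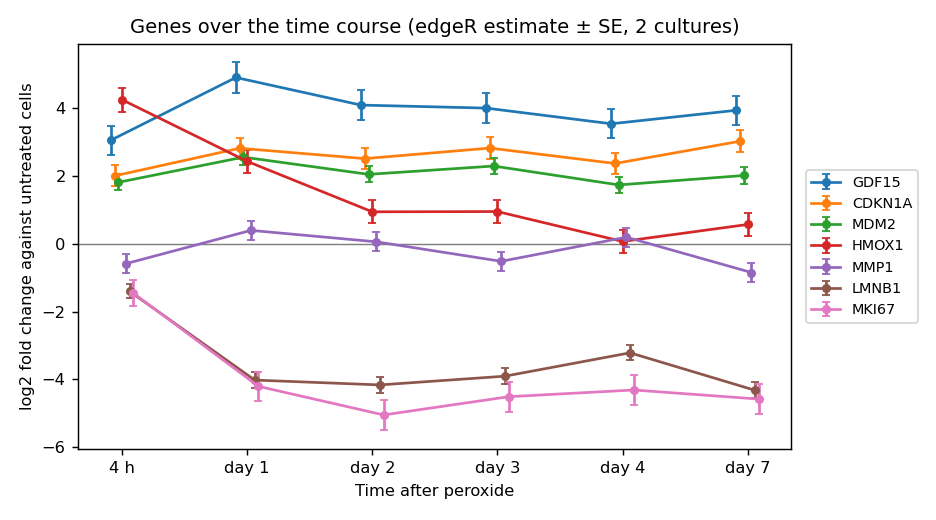
Log2 fold change against untreated cells (vertical axis) at each time after peroxide (horizontal axis) for 7 genes; points are edgeR estimates from 2 cultures and bars are standard errors. GDF15 stood at 3.06 at 4 h and 3.94 on day 7, MKI67 at -1.45 and -4.59, and HMOX1 at 4.26 and 0.57.

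Days 1 to 4 against untreated cells asked how the response went on. CDKN1A stayed high, with log2 fold changes of 2.82, 2.52, 2.83 and 2.37 on days 1, 2, 3 and 4 (SE 0.31, 0.31, 0.31 and 0.31, n = 2, all called). MDM2 was raised by 2.56, 2.05, 2.30 and 1.74 and GDF15 by 4.91, 4.10, 4.01 and 3.54 on the same scale, all called. HMOX1 was called on day 1 (2.44 ± 0.34, adjusted p = 0.000322) and not on days 2, 3 and 4 (0.94, 0.95 and 0.07). The proliferation gene MKI67 fell by 4.21, 5.05, 4.51 and 4.32 and LMNB1 fell by 4.02, 4.17, 3.91 and 3.22 on the log2 scale. CDKN2A, COL1A1, IL6, IL8 and MMP1 were called on none of these 4 days. Calls numbered 2337, 2555, 2682 and 1764, of which 852, 942, 1040 and 610 were higher, and DESeq2 called 2608, 2888, 2965 and 2102. Between successive times, day 1 against 4 h gave 2582 calls (997 higher and 1585 lower), with falls of LDHC (-4.06), PTGS2 (-3.60) and MKI67 (-2.75) and rises of GDF15 (1.85) and KYNU (1.53), an enzyme of tryptophan breakdown. Day 2 against day 1 gave 7 calls, among them the collagen gene COL11A1 (1.52), MAN1C1 (1.5), MRVI1 (1.88), the chloride channel gene ANO1 (1.86) and the kinase gene DYRK3 (-1.32). By edgeR, day 3 against day 2 and day 4 against day 3 gave 0 calls each, with 830 and 792 genes at an unadjusted p under 0.05, and DESeq2 was not run on these steps. Steps between times were chosen after the data were seen, as were the genes named for them. With library totals in place of TMM factors, median log2 fold changes of all genes on days 1, 2, 3 and 4 were 0.23, 0.15, 0.13 and 0.09, and 65.6, 60.2, 54.4 and 49.2% of calls were higher, against 36.5, 36.9, 38.8 and 34.6% with them.

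Cell-cycle lists were almost wholly lower on each of these days. Of 54 G2/M genes 54, 54, 54 and 53 fell on days 1, 2, 3 and 4 (54, 54, 54 and 54 adjusted within the list), with adjusted p of 0.0391, 0.0414, 0.042 and 0.0313 with an estimated correlation. S-phase genes fell in 40, 39, 39 and 38 of 42 cases (adjusted p 0.0476, 0.042, 0.0446 and 0.0408 with an estimated correlation). Homologous recombination genes fell in 20, 21, 21 and 20 of 24 (0.0335, 0.0302, 0.0289 and 0.0301 with an estimated correlation). For the nuclear genes known to fall in senescence the numbers were 13, 14, 13 and 12 of 14 (0.0335, 0.0302, 0.0304 and 0.0301 with an estimated correlation). Those were the 4 lists called with both correlations on each day. p53 targets rose in 31, 27, 30 and 19 of 39 cases (34, 31, 35 and 28 adjusted within the list, camera adjusted p 1.17e-26, 3.22e-21, 2.79e-23 and 4.82e-19), with adjusted p = 0.061, 0.102, 0.084 and 0.115 with an estimated correlation. NRF2 antioxidant genes that rose numbered 10, 8, 6 and 3 of 27, and unfolded-protein and ATF4 genes 11, 8, 7 and 5 of 23. Contractile genes fell in 15, 3, 4 and 3 of 26 cases, matrix genes in 13, 5, 2 and 3 of 37 and mitochondrially encoded genes in 6, 7, 1 and 1 of 15. Secreted factors of senescent cells rose in 5, 3, 5 and 3 and fell in 3, 2, 2 and 1 of 40 cases. At the preset correlation camera called 15, 14, 13 and 15 of 23 lists, and with an estimated correlation 4 on each day. Leaving out any 1 sample lowered every count, to the ranges in the closing part. Without the replicate block the counts were 1136, 1254, 1331 and 869.

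Day 7 against untreated cells asked which genes marked the late arrest. GDF15 rose 15.4-fold (3.94 ± 0.43, adjusted p = 2.31e-05). Its level was 80.9 ± 5.40 against 5.999 ± 4.90 CPM (mean ± SD, n = 2). CDKN1A rose 8.16-fold (3.03 ± 0.32, adjusted p = 1.47e-05). KIAA1199, a hyaluronan-binding protein gene, rose 13.9-fold (3.8 ± 0.48, adjusted p = 8.15e-05). PAPPA, whose product cleaves insulin-like growth factor binding proteins, rose 7.23-fold (2.85 ± 0.32, adjusted p = 2.49e-05). LMNB1 fell to 0.0498 of the untreated level (-4.33 ± 0.23, adjusted p = 2.37e-07), HMGB2, a chromatin protein gene, to 0.138 (-2.86 ± 0.34, adjusted p = 5.16e-05) and MKI67 to 0.0416 (-4.59 ± 0.44, adjusted p = 6.58e-06). MDM2 was 4.05-fold higher (2.02 ± 0.24, adjusted p = 5e-05). Estimates for HMOX1 (0.57), CDKN2A (0.03), COL1A1 (-0.43), IL6 (0.34) and IL8 (-0.50) were not called, and the collagenase gene MMP1 fell to 0.556 (-0.85 ± 0.28, adjusted p = 0.0475). Of 19753 tested genes 3858 were called, 1856 higher and 2002 lower, and DESeq2 called 4024. Others that rose most, again at a mean of at least 32 CPM, were C7orf69 (3.84), the p53-induced LINC01021 (3.66), the p53 target PTCHD4 (3.34), GALNT15 (3.31), CPA4 (3.00) and the ferritin light chain gene FTL (2.70). Those that fell most, under the same limit, were KIF18B (-4.86), CASC5 (-4.76), DEPDC1 (-4.69), BUB1B (-4.68), KIF2C (-4.67), CDCA8 (-4.65), KIF4A (-4.65), DLGAP5 (-4.64), FOXM1 (-4.63) and BUB1 (-4.61). Against day 1, 1358 genes were called, 905 higher, with rises of KIAA1199 (5.12), COL11A1 (3.39) and GALNT15 (3.25) and falls of the hyaluronan synthase gene HAS2 (-2.71) and E2F7 (-2.63). Day 7 against day 4 gave 4 calls, ANO1 (1.31), the growth factor gene EREG (-1.36), RP11-123O22.1 (-3.44) and RP11-1E6.1 (-3.04). These comparisons and their genes were chosen after the values were seen. Scaled by library totals instead of TMM factors, the median log2 fold change against untreated cells was 0.13 and 55.1% of calls were higher, against 48.1% with them. Without untreated replicate 1 there were 2066 calls, without untreated replicate 2 there were 1573, and without the replicate block 2089.

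On day 7 the lists of dividing cells were the lowest. G2/M genes were lower in 54 of 54 cases (0 and 54 adjusted within the list, median log2 -3.90, camera adjusted p = 4.58e-58, 0.0534 with an estimated correlation). S-phase genes were lower in 39 of 42 (0 and 39 adjusted within the list, median log2 -2.58, camera adjusted p = 2.47e-38, 0.0534 with an estimated correlation), with RRM2, a ribonucleotide reductase gene, at -4.11. Homologous recombination genes fell in 22 of 24 cases (1 and 22 adjusted within the list, median log2 -2.83, camera adjusted p = 1.87e-26, 0.0464 with an estimated correlation), the helicase gene BLM (-3.92) and RAD51AP1 (-3.88) the furthest. The nuclear genes known to fall in senescence did so in 13 of 14 cases (0 and 14 adjusted within the list, median log2 -2.05, camera adjusted p = 2.7e-16, 0.0464 with an estimated correlation). Replication-dependent histone genes had 1 higher and 15 lower of 22 (2 and 16 adjusted within the list, median log2 -2.81, camera adjusted p = 4.01e-08, 0.205 with an estimated correlation). Of 39 p53 targets 31 rose and 1 fell (33 and 1 adjusted within the list, median log2 1.2, camera adjusted p = 6e-18, 0.143 with an estimated correlation). FOXO and quiescence genes rose in 7 of 23 cases (10 and 0 adjusted within the list, median log2 0.82, camera adjusted p = 0.000519, 0.287 with an estimated correlation). Lysosome and autophagy genes rose in 8 of 25 cases (8 and 0 adjusted within the list, median log2 0.37, camera adjusted p = 0.00226, 0.421 with an estimated correlation). Interferon response genes had 5 higher and 2 lower of 20 (10 and 3 adjusted within the list, median log2 0.80, camera adjusted p = 0.00618, 0.433 with an estimated correlation), IFIT2 (2.87) and TRIM22 (2.23) among the former. Matrix genes fell in 10 and rose in 2 of 37 cases (2 and 10 adjusted within the list, median log2 -0.40, camera adjusted p = 0.00577, 0.747 with an estimated correlation), the elastin gene ELN (-2.23) against COL11A1 (1.92). TGF-beta response genes fell in 9 of 21 cases (1 and 9 adjusted within the list, median log2 -0.46, camera adjusted p = 0.0133, 0.259 with an estimated correlation). Secreted factors had 7 higher and 5 lower of 40 and were not called as a list (adjusted p = 0.492). Among them MMP10 was called lower (adjusted p = 0.0219), at 0.0420 ± 0.00824 against 0.842 ± 1.19 CPM, too few counts for a fold change, and its direction was reversed without untreated replicate 1 (adjusted p = 0.869). NRF2 genes had 5 higher of 27 and unfolded-protein and ATF4 genes 4 of 23. Kinase inhibitors had 3 higher of 7 with CDKN2C lower (-3.79), and contractile genes 4 lower of 26, including the smooth-muscle regulator MYOCD (-2.10). Those 4 lists were not called. Median, mean and camera direction differed in sign for immediate early genes (0.08, 0.17 and down), heat shock genes (0.07, 0.03 and down) and endothelial markers (median 0.03, mean -0.05).

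**Figure D2:**
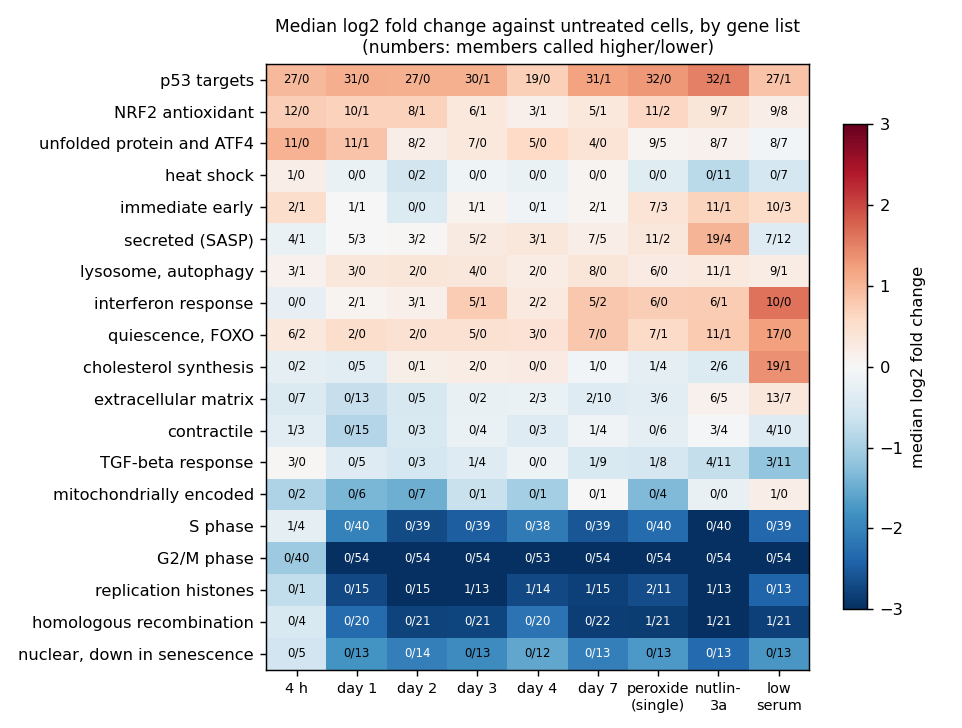
Median log2 fold change against untreated cells (colour) of each gene list, in 1 column per time point or single-exposure condition, with the numbers of members called higher and lower in each square. The G2/M list had a median of -1.09 at 4 h and -3.90 on day 7 and the p53 targets 0.97 and 1.2.

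Several genes that rose at 4 h, LDHC the first, are little expressed in untreated cells and lie beside an expressed gene, so the place of such genes was examined, a comparison chosen after the data were seen. LDHC lies downstream of the lactate dehydrogenase gene LDHA on the same strand, SEMA4A (log2 fold change 5.18) downstream of LMNA, SNX31 (4.85) of PABPC1, FNDC7 (5.34) of PRPF38B and MOBP (5.25), a myelin protein gene, of RPSA. Among genes under 5 CPM in untreated cells, 156 of 515 (30.3%) directly downstream of an expressed gene on the same strand were called higher at 4 h. In other positions beside an expressed gene 118 of 845 (14.0%) were called higher, a ratio of 2.17 (Fisher's exact test across genes, two-sided p = 7.28e-13, genes not being independent replicates). With no expressed neighbour 192 of 1339 (14.3%) were called higher. On day 1 the ratio was 1.79 (9.13% against 5.09%, exact p = 0.00474) and on day 7 it was 1.07 (14.0% against 13.0%, exact p = 0.623). Gene positions came from an annotation of another genome build matched by gene identifier, which placed 13860 of 19753 tested genes.

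**Figure D3:**
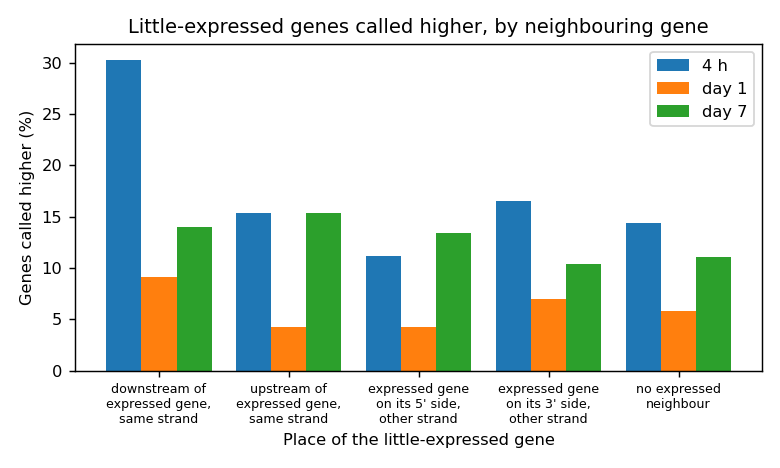
Percent of little-expressed genes called higher (vertical axis) by their place beside an expressed gene (horizontal axis), with a bar for each of 4 h, day 1 and day 7. At 4 h the share was 30.3% downstream on the same strand and 14.3% with no expressed neighbour.

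In the single exposure, peroxide-treated cells against untreated cells asked which genes senescence after oxidative stress changed. CDKN1A rose 5.71-fold (2.51 ± 0.17, adjusted p = 2.07e-05, 286 ± 130 against 49.2 ± 18.3 CPM, mean ± SD, n = 2). MDM2 rose 5.71-fold (2.51 ± 0.20, adjusted p = 4.04e-05) and GDF15 14.6-fold (3.87 ± 0.41, adjusted p = 0.000213). ICAM1, which encodes an adhesion molecule for leukocytes, rose 8.15-fold (3.03 ± 0.77, adjusted p = 0.0195) and TXNIP, an inhibitor of thioredoxin, 7.18-fold (2.85 ± 0.31, adjusted p = 0.000267). The mitotic kinase gene CDK1 fell to 0.0208 of the untreated level (-5.59 ± 0.30, adjusted p = 1.13e-05) and LMNB1 to 0.0585 (-4.09 ± 0.27, adjusted p = 1.76e-05). Estimates for CDKN2A (-0.28), IL6 (0.91), IL8 (-0.37), MMP1 (-1.03), COL1A1 (-0.92) and HMOX1 (0.69) were not called. Of 14256 tested genes 3583 were called, 1678 higher and 1905 lower, and DESeq2 called 2524. With a mean of at least 32 CPM, the genes that rose most after GDF15 were PTCHD4 (3.32), PAPPA (2.93), HIST1H2AC (2.92), TXNIP (2.85), LURAP1L (2.84) and CYP1B1 (2.52), MDM2, CDKN1A and KIAA1199 (2.42). Under that limit those that fell most after CDK1 were KIF18B (-5.19), PBK (-5.10), DEPDC1 (-4.94) and KIF4A (-4.83). With library totals in place of TMM factors, the median log2 fold change of all genes was 0.13 and 59.6% of calls were higher, against 46.8% with them. Leaving out untreated replicate 1 gave 1687 calls and leaving out untreated replicate 2 gave 1729. The peroxide replicates differed in cell make-up, with 18.0% and 65.7% of cells in the state 4 described with the cell states.

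The list of p53 targets had 39 measured genes, of which 32 rose and 0 fell after peroxide (34 and 0 adjusted within the list, median log2 1.29, camera adjusted p = 5.18e-19, 0.146 with an estimated correlation). All 54 of 54 measured G2/M genes fell (0 and 54 adjusted within the list, median log2 -4.15, camera adjusted p = 3.89e-44, 0.146 with an estimated correlation). So did 40 of 42 S-phase genes (0 and 40 adjusted within the list, median log2 -2.31, camera adjusted p = 1.59e-26, 0.12 with an estimated correlation). Homologous recombination genes fell in 21 and rose in 1 of 24 cases (1 and 21 adjusted within the list, median log2 -2.85, camera adjusted p = 1.61e-17, 0.12 with an estimated correlation). Nuclear genes known to fall in senescence did so in 13 of 13 (0 and 13 adjusted within the list, median log2 -1.73, camera adjusted p = 9.72e-14, 0.12 with an estimated correlation). NRF2 antioxidant genes had 11 higher and 2 lower of 25 (14 and 4 adjusted within the list, median log2 0.62, camera adjusted p = 0.000903, 0.352 with an estimated correlation). FOXO and quiescence genes had 7 higher of 22 (7 and 1 adjusted within the list, median log2 0.58, camera adjusted p = 0.00207, 0.146 with an estimated correlation). Secreted factors had 11 higher and 2 lower of 35 (12 and 3 adjusted within the list, median log2 0.34, camera adjusted p = 0.0218, 0.514 with an estimated correlation), ICAM1 up and IL11 (-2.54) down. Interferon genes rose in 6 of 16 cases (8 and 0 adjusted within the list, median log2 0.74, camera adjusted p = 0.0067, 0.452 with an estimated correlation). Mitochondrially encoded genes fell in 4 of 15 cases (0 and 12 adjusted within the list, median log2 -1.32, camera adjusted p = 9.09e-06, 0.452 with an estimated correlation). The median mitochondrial share per cell was 0.564 and 0.582% in peroxide-treated and 0.655 and 1.86% in untreated replicates. TGF-beta response genes fell in 8 of 20 cases (1 and 10 adjusted within the list, median log2 -0.51, camera adjusted p = 0.00291, 0.352 with an estimated correlation). Matrix genes had 3 higher and 6 lower of 37 (camera adjusted p = 0.0067, 0.599 with an estimated correlation), COL11A1 (1.67) and COL14A1 (1.5) up. Contractile genes had 6 lower of 26 (camera adjusted p = 0.00342, 0.533 with an estimated correlation), MYOCD (-2.73) lowest. Immediate early genes had 7 higher and 3 lower of 22 (camera adjusted p = 0.0234, 0.512 with an estimated correlation), ATF3 (2.17) and FOSB (1.81) up. Lysosome genes had 6 higher of 24 (camera adjusted p = 0.0215, 0.397 with an estimated correlation), SQSTM1 (2.19) highest. Histone genes had 2 higher and 11 lower of 16, HIST1H1B (-4.62) lowest (camera adjusted p = 8.53e-06, 0.229 with an estimated correlation). Heat shock genes had 0 calls of 16 but a lower rank as a list (camera adjusted p = 0.0072, 0.452 with an estimated correlation). Lists not called were ATF4 and unfolded protein (9 up and 5 down of 23, TRIB3 at 2.92) and cholesterol synthesis (1 up and 4 down of 23, INSIG1 at -1.22). Also not called were kinase inhibitors (CDKN2C at -3.26) and pericyte genes (2 down of 8, CSPG4 at -1.33).

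Nutlin-3a against untreated cells asked what arrest without oxidative damage changed. CCND2, a D-type cyclin gene, rose 70.9-fold (6.15 ± 0.34, adjusted p = 3.69e-06, 103 ± 15.6 against 1.40 ± 0.179 CPM, n = 2). The adhesion molecule gene VCAM1 rose 69.4-fold (6.12 ± 0.83, adjusted p = 0.000515) and MDM2 11.2-fold (3.48 ± 0.21, adjusted p = 4.96e-06). CDKN1A rose 4.83-fold (2.27 ± 0.17, adjusted p = 1.77e-05), and MKI67 fell to 0.00467 of the untreated level (-7.74 ± 0.41, adjusted p = 3.34e-06). The interleukin gene IL6 rose 4.48-fold (2.16 ± 0.29, adjusted p = 0.000465), while MMP1 fell to 0.151 (-2.73 ± 0.41, adjusted p = 0.000833) and ID1, an inhibitor of differentiation, to 0.0244 (-5.36 ± 0.27, adjusted p = 2.83e-06). Calls numbered 5758, 2768 higher and 2990 lower (4114 by DESeq2). Of 39 p53 targets 32 rose and 1 fell (33 and 1 adjusted within the list, median log2 1.52, camera adjusted p = 8.09e-17, 0.173 with an estimated correlation). Secreted factors had 19 higher and 4 lower of 35 (21 and 4 adjusted within the list, median log2 1.015, camera adjusted p = 0.000883, 0.451 with an estimated correlation), ICAM1 (4.17) highest and IL11 (-3.82) lowest. G2/M genes fell in 54 of 54 cases (0 and 54 adjusted within the list, median log2 -5.14, camera adjusted p = 1.7e-32, 0.211 with an estimated correlation). Heat shock genes fell in 11 of 16 (0 and 12 adjusted within the list, median log2 -0.82, camera adjusted p = 0.00035, 0.406 with an estimated correlation). FOXO genes rose in 11 of 22 cases (11 and 1 adjusted within the list, median log2 0.78, camera adjusted p = 0.000676, 0.145 with an estimated correlation). TGF-beta response genes fell in 11 of 20 cases (4 and 11 adjusted within the list, median log2 -0.73, camera adjusted p = 0.00801, 0.406 with an estimated correlation). Camera called 13 of 21 lists at the preset correlation and 0 with an estimated one. Mitochondrially encoded genes (0 up and 0 down) and NRF2 genes (9 up and 7 down of 25) were among those not called. Median and mean differed in sign for pericyte genes (0.15 and -0.13) and kinase inhibitors (0.12 and -0.11), where CDKN2B rose (2.55). Scaled by library totals, not TMM factors, the median log2 fold change of all genes was -0.11 and 41.0% of calls were higher, against 48.1% with them. Calls fell when any 1 sample was left out (range in the closing part).

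Quiescent against untreated cells asked what reversible arrest in low serum changed. The matrix gene COL14A1 rose 21.8-fold (4.45 ± 0.44, adjusted p = 6.98e-05, 209 ± 4.58 against 10.1 ± 4.46 CPM, n = 2). FMO2, a flavin monooxygenase gene, was called higher at 73.4 ± 9.48 against 0.128 ± 0.181 CPM (adjusted p = 8.04e-05), with too few untreated counts for a fold change. MMP1 fell to 0.0151 of the untreated level (-6.05 ± 0.60, adjusted p = 7.05e-05). ID1 was called lower at 0.111 ± 0.157 against 53 ± 7.03 CPM (adjusted p = 4.92e-06), with too few quiescent counts for a fold change. CDKN1C, the gene of the kinase inhibitor p57, rose 10.1-fold (3.34 ± 0.39, adjusted p = 0.000187), and CDKN2A, whose products are p16 and p14ARF, rose 1.79-fold (0.84 ± 0.17, adjusted p = 0.00396). Calls numbered 6223, 3027 higher and 3196 lower (4794 by DESeq2). Cholesterol synthesis genes rose in 19 of 23 cases (19 and 1 adjusted within the list, median log2 1.38, camera adjusted p = 4.66e-07, 0.353 with an estimated correlation). FOXO and quiescence genes rose in 17 of 22 cases (17 and 0 adjusted within the list, median log2 1.24, camera adjusted p = 2.54e-06, 0.138 with an estimated correlation). Interferon genes rose in 10 of 16 cases (10 and 0 adjusted within the list, median log2 1.63, camera adjusted p = 0.000192, 0.318 with an estimated correlation). Matrix genes had 13 higher and 7 lower of 37 and were not called as a list (camera adjusted p = 0.0824). p53 targets rose in 27 of 39 cases (27 and 1 adjusted within the list, median log2 0.85, camera adjusted p = 4.66e-07, 0.318 with an estimated correlation). Secreted factors had 7 higher and 12 lower of 35 (camera adjusted p = 0.368). G2/M genes fell in 54 of 54 cases (0 and 54 adjusted within the list, median log2 -3.82, camera adjusted p = 1.42e-29, 0.279 with an estimated correlation). Of 21 lists 15 were called at the preset correlation and 0 with an estimated one. The ATF4 list had a median of -0.09 and a mean of 0.08. Fewer genes were called with any 1 sample left out (range in the closing part).

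Peroxide against nutlin-3a asked what set senescence after oxidative stress apart from arrest through p53 alone. ID1 was 19.0-fold higher after peroxide (4.25 ± 0.28, adjusted p = 0.000608, 24.7 ± 5.40 against 1.29 ± 0.164 CPM, n = 2). MKI67 was 9.29-fold higher (3.22 ± 0.47, adjusted p = 0.0125, 18.2 ± 9.51 against 1.87 ± 0.664 CPM). The NRF2 target NQO1, a quinone reductase gene, was 4.56-fold higher (2.19 ± 0.20, adjusted p = 0.00313) and FTL 2.87-fold (1.52 ± 0.15, adjusted p = 0.00514). MDM2 was lower, at 0.511 of the nutlin-3a level (-0.97 ± 0.19, adjusted p = 0.0257), as was VCAM1 at 0.181 (-2.47 ± 0.61, adjusted p = 0.0456). Of the interleukin genes, IL6 stood at 0.419 (-1.25 ± 0.26, adjusted p = 0.0303) and IL1B at 0.113 (-3.15 ± 0.62, adjusted p = 0.0268). CDKN1A (0.24 ± 0.16, adjusted p = 0.364), GDF15 (0.95 ± 0.32, adjusted p = 0.105) and LMNB1 (1.51 ± 0.42, adjusted p = 0.0629) were not called. Calls numbered 976, 463 higher and 513 lower (795 by DESeq2), but 54 without the replicate block, whose numbers are not shown to pair these cultures. Without it ID1, MKI67 and NQO1 were still called and FTL, MDM2, VCAM1, IL6 and IL1B were not. G2/M genes were higher in 17 of 54 cases (26 and 0 adjusted within the list, median log2 0.97, camera adjusted p = 6.25e-09, 0.496 with an estimated correlation). S-phase genes were higher in 7 of 42 (15 and 0 adjusted within the list, median log2 0.74, camera adjusted p = 4.94e-08, 0.483 with an estimated correlation). p53 targets were lower in 9 of 39 cases (3 and 15 adjusted within the list, median log2 -0.31, camera adjusted p = 1.57e-05, 0.483 with an estimated correlation). NRF2 genes were higher in 5 of 25 (9 and 1 adjusted within the list, median log2 0.29, camera adjusted p = 0.00036, 0.483 with an estimated correlation). Secreted factors had 3 higher and 5 lower of 35 (5 and 10 adjusted within the list, median log2 -0.24, camera adjusted p = 0.0229, 0.666 with an estimated correlation). Matrix genes had 1 higher and 2 lower of 37 (1 and 3 adjusted within the list, median log2 -0.42, camera adjusted p = 8.99e-06, 0.666 with an estimated correlation). Mitochondrially encoded genes had 0 calls each way of 15 and ranked low as a list (0 and 8 adjusted within the list, median log2 -1.26, camera adjusted p = 4.94e-08, 0.496 with an estimated correlation). Cholesterol synthesis genes had a median of -0.12, a mean of 0.02 and a downward camera direction (adjusted p = 0.942). Without TMM factors there were 1639 calls, the median log2 fold change of all genes was 0.22 and 79.1% of calls were higher, against 47.4% with them. The number of calls rested on single samples: edgeR gave 4 without nutlin-3a replicate 1, ID1 (4.52) and ID3 (2.23) among them, and 0 without nutlin-3a replicate 2, where 1692 genes had an unadjusted p under 0.05. There were 3327 and 1548 without peroxide replicates 1 and 2. ID1 and ID3 were chosen here after their values were seen, and DESeq2 was not run on the reduced sets.

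Peroxide against quiescence asked what set senescence after oxidative stress apart from reversible arrest. MMP1 was 32.4-fold higher after peroxide (5.02 ± 0.62, adjusted p = 0.000858, 48.6 ± 25.9 against 1.36 ± 1.22 CPM, n = 2). ID1 was called higher at 24.7 ± 5.40 against 0.111 ± 0.157 CPM (adjusted p = 5.71e-05), with too few quiescent counts for a fold change. CDKN1A was 2.67-fold (1.42 ± 0.16, adjusted p = 0.000645), GDF15 4.04-fold (2.01 ± 0.35, adjusted p = 0.00418) and IL8, a neutrophil-attracting chemokine gene, 7.07-fold higher (2.82 ± 0.76, adjusted p = 0.0275). CDKN2A was lower, at 0.461 of the quiescent level (-1.12 ± 0.17, adjusted p = 0.00234), as were CDKN1C at 0.286 (-1.81 ± 0.32, adjusted p = 0.00416) and SCD, a fatty acid desaturase gene, at 0.0696 (-3.85 ± 0.20, adjusted p = 3.5e-05). Calls numbered 3356, 1588 higher and 1768 lower (2242 by DESeq2). Cholesterol synthesis genes were lower in 18 of 23 cases (0 and 20 adjusted within the list, median log2 -1.51, camera adjusted p = 4.45e-13, 0.559 with an estimated correlation). Matrix genes were lower in 16 of 37 cases (1 and 20 adjusted within the list, median log2 -0.74, camera adjusted p = 1.09e-05, 0.76 with an estimated correlation). Mitochondrially encoded genes were lower in 9 of 15 (0 and 15 adjusted within the list, median log2 -1.64, camera adjusted p = 4.7e-07, 0.559 with an estimated correlation). Secreted factors were higher in 17 and lower in 4 of 35 cases (18 and 5 adjusted within the list, median log2 1.38, camera adjusted p = 0.000435, 0.559 with an estimated correlation). For p53 targets the numbers were 14 and 1 of 39 (19 and 4 adjusted within the list, median log2 0.36, camera adjusted p = 6.16e-05, 0.559 with an estimated correlation). FOXO genes were lower in 12 of 22 cases (3 and 14 adjusted within the list, median log2 -0.82, camera adjusted p = 0.000585, 0.537 with an estimated correlation). Interferon genes were lower in 6 of 16 (0 and 7 adjusted within the list, median log2 -0.68, camera adjusted p = 0.00624, 0.559 with an estimated correlation). G2/M genes had 4 higher and 3 lower of 54 (camera adjusted p = 0.316). Under library totals instead of TMM factors, the median log2 fold change of all genes was 0.17 and 63.9% of calls were higher, against 47.3% with them. Without quiescence replicate 1 there were 1115 calls, without quiescence replicate 2 there were 1027, and without the replicate block 2022.

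In the double exposure, with 1 culture per condition, CPM in peroxide-treated cells were divided by those in nutlin-3a-treated cells, and the intervals cover counting error only. The ratio was 16.5 (95% interval 10.8 to 26.4) for CLGN, a chaperone gene, 9.57 (95% interval 7.37 to 12.6) for the phosphodiesterase gene PDE4D and 3.04 (95% interval 2.62 to 3.54) for GDF15. It was 0.921 (95% interval 0.865 to 0.982) for CDKN1A, 0.295 (95% interval 0.280 to 0.310) for MDM2 and 0.288 (95% interval 0.274 to 0.302) for the collagen gene COL1A1. MKI67 had 36 counts after peroxide and 0 after nutlin-3a, at least 15.3-fold higher over a floor of 3 counts (lower 95% limit 11.8), and IL8 had 25 and 0, at least 10.6-fold higher by that floor (lower 95% limit 8.01). INPP5D had 0 counts against 110, at least 28.8-fold lower by it (upper 95% limit of the ratio 0.0435). Summed NRF2 counts had a ratio of 3.33 (interval 3.26 to 3.40, median log2 1.27, percentile 100) and p53 targets 0.674 (interval 0.659 to 0.690, median log2 -0.26, percentile 0.010), where the percentile places the median log2 ratio of the list among those of 10000 random lists of matched expression. Matrix genes stood at 0.575 (interval 0.568 to 0.583, median log2 -0.55, percentile 0) and mitochondrially encoded genes 0.547 (interval 0.540 to 0.554, median log2 -1.31, percentile 0), and pericyte markers, with 179 counts against 669 (RGS5 alone 41 against 410), at 0.341 (interval 0.287 to 0.403, median log2 -0.64, percentile 0.920). G2/M genes stood at 1.44 (interval 1.37 to 1.51, median log2 0.60, percentile 99.9), S-phase genes at 1.38 (interval 1.28 to 1.49, median log2 0.61, percentile 99.2) and the ATF4 list at 1.22 (interval 1.18 to 1.26, median log2 0.99, percentile 100). Against quiescence the ratios were 4.94 (95% interval 4.42 to 5.54) for CDKN1A, 19.8 (95% interval 15.9 to 24.8) for MMP1 and 71.2 (95% interval 24.0 to 348) for ID1, which had 3 counts in quiescent cells. p53 targets stood at 2.13 (interval 2.06 to 2.20, median log2 0.86, percentile 100), cholesterol synthesis at 0.223 (interval 0.212 to 0.234, median log2 -2.13, percentile 0), matrix genes at 0.491 (interval 0.484 to 0.497, median log2 -1.10, percentile 0) and heat shock genes at 1.66 (interval 1.61 to 1.70, median log2 0.72, percentile 99.8). Endothelial markers, with 35 counts against 116, stood at 0.339 (interval 0.226 to 0.499), and too few were counted for a percentile. For NRF2 genes the summed ratio was 1.42 and the median log2 ratio -0.07, at percentile 13.1.

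Whether cells of one treatment were alike was asked by grouping cells on a random 50% of the counts and comparing genes on the held-out rest. Single-exposure cells formed 6 states, clusters on genes that differ between conditions, so their shares are given as values and no comparison between conditions is drawn from them. State 1 held 97.6 and 97.7% of nutlin-3a-treated cells in replicates 1 and 2 and 71.3 and 30.6% of peroxide-treated cells. State 4 held 18.0% (interval 16.4 to 19.7) and 65.7% (interval 63.7 to 67.8) of peroxide-treated cells. It held 1.17 and 0.949% of untreated cells, 1.14 and 0.166% of nutlin-3a-treated cells and 0.0387 and 0.0449% of quiescent cells. State 2 held 96.7 and 93.8% of quiescent cells. State 3, the cycling-like one with 5 cell-cycle genes among its 10 leading genes, held 76.6 and 63.6% of untreated and 4.20 and 1.13% of peroxide-treated cells, and state 5 held 20.1 and 32.04% of untreated cells. Within peroxide-treated cells, state 4 had higher KYNU (4.10 ± 0.34, adjusted p = 2.18e-07), CLGN (3.64 ± 0.27, adjusted p = 7.88e-08), CDKN1A (2.14 ± 0.18, adjusted p = 1.98e-07) and GDF15 (3.04 ± 0.27, adjusted p = 6.65e-07) than state 1. It had lower KIAA1199 (-4.30 ± 0.57, adjusted p = 3.81e-05), ELN (-3.99 ± 0.54, adjusted p = 4.72e-05) and COL1A1 (-1.83 ± 0.29, adjusted p = 0.00028). Calls numbered 2487, 1095 higher and 1392 lower, and DESeq2 called 1697. MDM2 (1.28), HMGB2 (1.90) and HMOX1 (1.47) were higher and MKI67 lower (-2.40). Called higher in state 4 were 18 of 23 NRF2 genes (1 lower), 18 of 39 p53 targets and 9 of 23 ATF4 genes (2 lower), against 1095 of 11836 genes in all. Called lower were 32 of 37 matrix, 16 of 25 contractile and 13 of 15 mitochondrially encoded genes and 12 of 32 secreted factors (4 higher), against 1392 in all, and no list was tested as a whole between states. The median log2 fold change of all genes without TMM factors was 0.23 and 68.7% of calls were higher, against 0.01 and 44.0% with them, a shift smaller than the median of any list named here (-0.56 for secreted factors, the nearest to 0). Sums of several states of a culture enter the fits of states as separate samples, with the replicate number and not the culture as the block, so their p-values rest on more degrees of freedom than the cultures give. With each culture as its own block, an alternative chosen after the values were seen, there were 3510 calls, 1621 higher and 1889 lower.

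Within state 1, peroxide-treated were compared with nutlin-3a-treated cells. Peroxide-treated cells with higher CDKN1A and MDM2 lay in state 4, so those left in state 1 were selected for lower levels, unlike nutlin-3a-treated cells. Over all cells CDKN1A was 0.24 against nutlin-3a and not called. MMP1 (1.82 ± 0.41, adjusted p = 0.0248) and the Wnt antagonist gene SFRP1 (1.57 ± 0.19, adjusted p = 0.00026) were higher after peroxide, and MDM2 (-1.55 ± 0.14, adjusted p = 1.78e-05) and CDKN1A (-0.95 ± 0.17, adjusted p = 0.00696) were lower. Calls numbered 261, 75 higher and 186 lower (139 by DESeq2 and 54 without the replicate block). Of 39 p53 targets 0 were higher and 17 lower. Without TMM factors the median log2 fold change was 0.09 and 49.0% of calls were higher, against 0.00 and 28.7% with them.

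**Figure D4:**
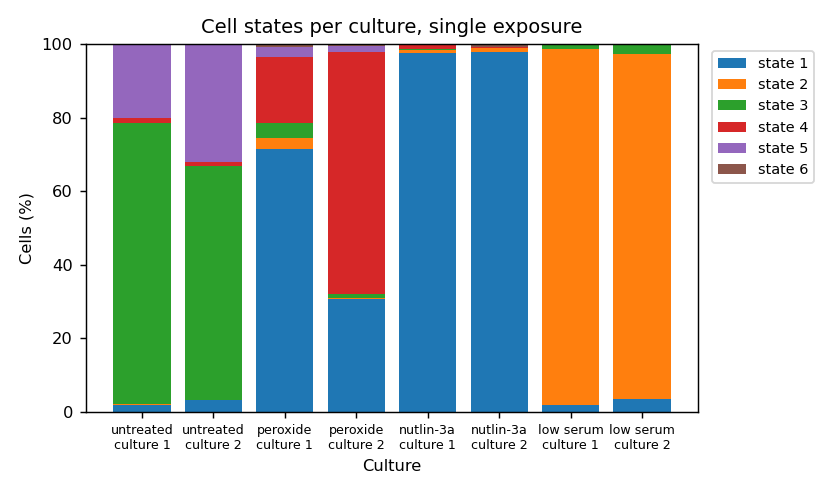
Share of cells in percent (vertical axis) in each of 6 cell states for the 8 cultures of the single exposure, stacked to the whole of each culture. State 4 made up 18.0% and 65.7% of the peroxide-treated cultures.

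Time-course cells formed 11 states, of which 3, 5 and 6 met the count of cell-cycle genes for a cycling-like name. State 5 consisted of 92.4% 4 h cells, and state 6 had a median of 1206 UMIs against 3676 over all cells and drew 91.9% of its cells from replicate 1. State 3 held 52.4 and 76.7% of untreated cells in replicates 1 and 2, state 5 42.0 and 72.7% of 4 h cells. State 1 held 39.4 and 44.5% of day 2 and 35.7 and 41.5% of day 7 cells, and state 2 42.0 and 62.2% of day 1 and 21.1 and 2.72% of day 7 cells. At day 7, state 2 against state 1 had higher CLGN (4.22 ± 0.39, adjusted p = 1.85e-11), GDF15 (3.19 ± 0.41, adjusted p = 1.32e-07) and CDKN1A (2.14 ± 0.29, adjusted p = 2.93e-07) and lower KIAA1199 (-4.60 ± 0.61, adjusted p = 2.49e-07). These were among 1443 calls (567 higher and 876 lower, 1821 by DESeq2). State 2 differed from state 1 in 162, 733, 1113, 1302 and 1443 genes on days 1, 2, 3, 4 and 7, in 34, 258, 447, 466 and 715 without the replicate block and 481, 1577, 2039, 2569 and 2803 with each culture as a block. NRF2 genes were higher in 4, 15, 15, 18 and 15 of 23 cases, p53 targets in 2, 10, 17, 22 and 20 of 39 and ATF4 genes in 9, 12, 13, 13 and 10 of 23. Matrix genes were lower in 4, 15, 19, 15 and 17 of 37 cases. Under library totals without TMM factors, the median log2 fold changes of state 2 against state 1 were 0.11, 0.17, 0.19, 0.17 and 0.24, and 55.4, 60.1, 65.7, 70.8 and 74.4% of calls were higher, against 47.5, 37.4, 41.1, 48 and 39.3% with them. With TMM factors the medians were 0.05, 0.02, 0.01, 0.00 and -0.03, and those of p53 targets, the nearest to 0 of the NRF2, p53 and ATF4 lists, were 0.33, 0.49, 0.71, 0.74 and 0.79.

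Other states of a time point were compared with its main state. In day 7 cells, state 7 against state 1 had higher H1F0 (3.85 ± 0.42, adjusted p = 8.45e-10), CLGN (3.85), FTL (3.48) and CDKN1A (3.13) and lower KIAA1199 (-3.71). NRF2 genes were higher in 18 of 23 cases and heat shock genes in 12 of 16 (4484 calls, 2205 higher, 5382 with each culture as a block and 2940 without a block). State 4 against state 1 had higher ALDOA (2.31 ± 0.30, adjusted p = 5.82e-07) and GAPDH (2.30), genes of glycolysis, and lower SDK1 (-1.42). All 15 of 15 mitochondrially encoded and 15 of 16 heat shock genes were higher (2295 calls, 1642 higher, 3998 and 2109 with each culture as a block, and 609 and 594 without a block). State 4 held 8.08% of day 7 cells of replicate 1, 7.79% in the first library of replicate 2 and 32.3% in the second. Median mitochondrial shares of day 7 cells were 0.688, 0.172 and 0.636% in that order and ribosomal RNA shares 4.12, 1.63 and 4.67%, so the library was not separated from the state. In 4 h cells, state 8 against state 5 had higher LDHC (4.40 ± 0.40, adjusted p = 2.51e-10), HK2 (3.12) and the oxygen sensor gene EGLN1 (2.67), and lower IL6 (-2.30), NRG1 (-2.28) and MDM2 (-1.19). There were 2939 calls (1488 higher, 3978 with each culture as a block and 1510 without a block). Immediate early genes were higher in 11 of 22 cases and p53 targets lower in 10 of 39. For day 7 state 7 the median log2 fold change without TMM factors was 0.15 and 69.1% of calls were higher, against -0.10 and 49.2% with them. For day 7 state 4 it was -0.12 and 76.5% of calls were higher, against -0.16 and 71.5% with them. For 4 h state 8 it was 0.22 and 74.2% of calls were higher, against 0.02 and 50.6% with them, and the list medians were -0.47 for p53 targets and 1.38 for immediate early genes.

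The difference between states 4 and 1 of the single exposure was compared with those of other cultures, a comparison chosen after the values were seen. Double-exposure cells formed 4 states, of which state 3 held 66.5% (520 of 782) and state 1 31.8% (249) of peroxide-treated cells, state 1 99.8% of nutlin-3a-treated cells and state 2 92.5% of quiescent cells. In peroxide-treated cells the ratio of state 3 to state 1 was above 1 for PDE4D (10.2), GDF15 (9.32), KYNU (7.85), CLGN (7.01), FTL (5.02), NQO1 (3.83) and CDKN1A (2.76), and below 1 for COL1A1 (0.300) and ACTG2 (0.0412, interval 0.00482 to 0.159, from 2 and 39 counts). KIAA1199, with 4 and 3 counts, and ELN, with 0 and 0, had too few for a ratio. Among genes with at least 50 counts over both of these states, 670 were called higher in state 4 of the single exposure, of which 615 (91.8%) had a ratio above 1 there, and 662 of 810 called lower (81.7%) had a ratio below 1, with r = 0.689 and rho = 0.597 across 4440 genes. For state 2 against state 1 of day 7 cells the shares were 1047 of 1088 (96.2%) higher and 1348 of 1381 (97.6%) lower, with r = 0.694 and rho = 0.711 across 11638 genes. The share of all genes above 1 is not given and ratios use library totals, so the double-exposure shares lack a no-change value. In each pair of states the first was the shallower over all conditions, and depth was not separated. Genes are not independent replicates.

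How many cells still cycled was asked with 6 genes of S phase to mitosis, MKI67, TOP2A, CENPF, TPX2, UBE2C and CDK1, after thinning each cell to 1000 UMIs. At least 1 UMI of these genes was found in 66.5% ± 11.6 of untreated time-course cells (mean ± SD, n = 2), 48.5% ± 7.90 of 4 h cells and 14.4% ± 8.88 of day 1 cells. On days 2, 3, 4 and 7 the shares were 5.97% ± 2.503, 7.67% ± 3.31, 8.15% ± 0.270 and 7.01% ± 0.708. The single exposure gave 65.7% ± 7.76 in untreated, 4.98% ± 1.38 in peroxide-treated, 2.20% ± 0.0555 in nutlin-3a-treated and 5.46% ± 1.48 in quiescent cells. The double exposure gave 6.65% (interval 5.01 to 8.63) of peroxide-treated, 2.76% (interval 1.88 to 3.90) of nutlin-3a-treated and 10.01% (interval 8.49 to 11.7) of quiescent cells. UMIs of immune-cell genes, which fibroblasts should lack, were found in 0 to 0.364% of cells over the same samples at the same thinned depth. In the single exposure the 6 genes summed over cells stood at a CPM of 144 and 92.4 in the peroxide replicates. Nutlin-3a replicates stood at 23.8 and 23.5, quiescent ones at 90.3 and 159 and untreated ones at 2540 and 2378. With 2 replicates per condition these shares were not tested.

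**Figure D5:**
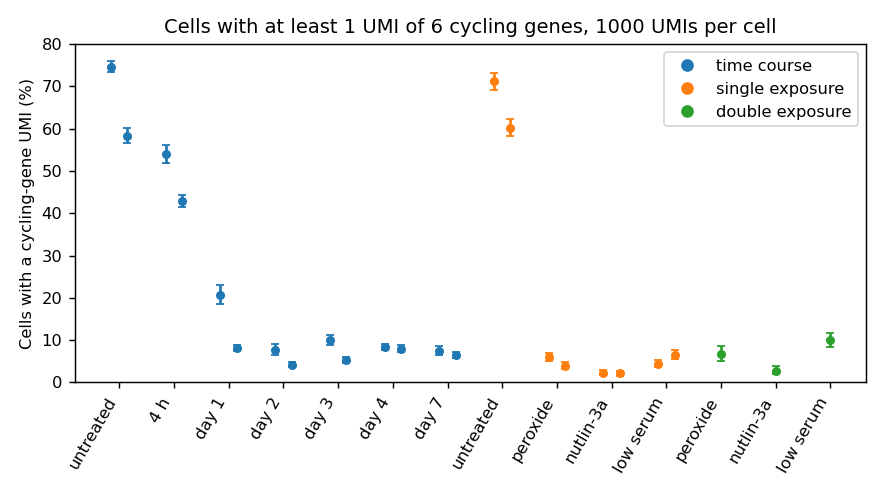
Percent of cells with at least 1 UMI of 6 cycling genes after thinning to 1000 UMIs (vertical axis), per condition; points are replicates, or the single culture of the double exposure, and bars are exact 95% intervals for counting error. Untreated time-course replicates stood at 74.7 and 58.3% and day 7 replicates at 7.52 and 6.51%.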

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

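The steps between time points were tested only after the first results were seen. Wells to which the barcode tables give no condition held cells with at least 1000 UMIs in each time-course library: 1586 in 4 wells of the library of replicate 1 and 13301 in 20 wells and 11606 in 18 wells of the libraries of replicate 2. They were singled out because a count of 0 would allow 3, and they held 8.14, 46.4 and 42.9% of the counts of those libraries; their condition is not known and they were left out. The change of MMP1 against untreated cells differed between day 7 and day 1 by -1.24 on the log2 scale (standard error 0.28, edgeR adjusted p = 0.0176), the test of the difference itself. That of HMOX1 differed between the same days by -1.86 (standard error 0.33, edgeR adjusted p = 0.00462).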

How the results depend on the processing

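The counts of state contrasts were recomputed only after their first values were seen, and the other alternatives were chosen beforehand. Without the replicate block, edgeR called 1385, 1136, 1254, 1331, 869 and 2089 genes at 4 h and on days 1, 2, 3, 4 and 7, 54 for peroxide against nutlin-3a and 2022 against quiescence, and stayed within 1.5 times for the other comparisons; the cause was not tested. With the libraries of replicate 2 kept apart and the library as the block, day 1 gave 3585, day 2 gave 3895 and day 4 gave 2800 calls, more samples entering the fit. From its first library alone, in which untreated cells numbered 551, 4 h gave 1928, day 3 gave 1532 and day 4 gave 1135. Peroxide against nutlin-3a gave 1639 calls without TMM factors and 2181 with no low-count filter; the cause was not tested.

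Leaving out each sample in turn gave 523 to 4531 calls at 4 h, 933 to 1155 on day 1, 987 to 1195 on day 2, 940 to 1507 on day 3, 738 to 959 on day 4 and 1573 to 3658 on day 7. In the single exposure the ranges were 1687 to 4345 for peroxide, 2651 to 3676 for nutlin-3a and 3717 to 4421 for quiescence against untreated cells, 0 to 3327 for peroxide against nutlin-3a and 1027 to 4312 against quiescence. The lone sample left in a group is then assumed to vary like the others. Fewer samples were tested, and the cause of rises was not tested.

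With an estimated correlation camera called 0 lists at 4 h, 4 on each of days 1, 2, 3 and 4, 2 on day 7, and 0 for each of the 5 single-exposure comparisons; the cause was not tested. The time course gave 7 states at resolution 0.25, and at resolution 1 the states led by double-exposure peroxide-treated cells held 94.4% of them. Shares of cycling cells moved with their definition: with at least 2 UMIs, thinned to 2000 UMIs and unthinned they were 0.0404, 4.41 and 5.83% for nutlin-3a, 1.84, 7.93 and 9.38% for peroxide and 44.6, 78.6 and 79.7% for untreated time-course cells; thinning to 2000 UMIs also leaves out cells with fewer.

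Double-exposure ratios of peroxide to nutlin-3a were, for matrix genes, 0.564 at a minimum of 500 UMIs, 0.620 at 2000 and 0.515 with TMM factors, for NRF2 genes 3.13 at 2000 and 2.98 with TMM, and for p53 targets 0.622 and 0.604. Against quiescence matrix genes gave 0.481, 0.544 and 0.456, NRF2 genes 1.28 and 1.32 and p53 targets 1.92 and 1.98; the cause was not tested. TGF-beta response genes against nutlin-3a passed to 1.007 at 2000 UMIs and contractile genes to 0.930 with TMM factors, across a ratio of 1. Leaving out samples moved the fitted value of MMP10 on day 7 between -4.76 and 0.98, the latter reversed (adjusted p = 0.869, without untreated replicate 1), which measures no size at counts this low. Counted per named gene and comparison, 426 values kept their direction and side of the threshold under DESeq2 and 23 became weaker; without TMM factors these were 444 and 9, without the replicate block 376 and 82, and over each sample left out in turn 1494 and 314. With few counts, smaller changes of a gene of low level were not detectable.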

Other observations

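The tests on free RNA and doublets were chosen only after their results were seen, clustering at equal depth after a comparison of shares by depth that had little room to go the other way, and the other tests after the median depth of the states and some leading genes were seen. Peroxide-treated cells of the single exposure fell into states 1 and 4, and depth, wells and loss of cytoplasmic RNA were weighed as technical causes. Depth as the whole cause is argued against: with every cell thinned to 1000 UMIs and clustered again, the main cluster of state 4 cells took 92.7 and 95.9% of them in replicates 1 and 2 against 1.30 and 2.46% of state 1 cells, at least 39.03 times the share. The share in state 4 did fall with depth, from 20.9 to 13.3% in replicate 1 and from 78.5 to 47.5% in replicate 2 between the third of cells with the fewest UMIs and the third with the most. At 1000 UMIs per cell the share in that cluster fell alike between the same cells, from 19.8 to 13.6% and from 77.1 to 46.5%, so depth at clustering does not make this trend, and what does stays open. The lowest well held 0.705 of the highest well's share or more in both replicates, which argues against barcoding wells, and ribosomal protein mRNAs, which are cytoplasmic, had a median log2 fold change of 0.57 in state 4, which argues against a general loss of cytoplasmic RNA. Called lower there were 32 of 37 matrix and 13 of 15 mitochondrially encoded genes, and its cells were shallower (a median of 1852 UMIs against 2318 over both states' cells of all conditions), so a loss of part of the RNA stays open. A biological split of the arrested cells, with 18 of 23 NRF2 genes and 18 of 39 p53 targets called higher in state 4, may stand beside it as a hypothesis; why its share differed between replicates was not tested.

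Little-expressed genes were called higher 4 h after peroxide in 30.3% of cases downstream of an expressed gene on the same strand and in 14.0% in other positions, and a candidate explanation of the difference is transcription running on from the gene upstream. The ratio of these shares was 2.17, over the 2 times asked for, whereas a general gain of low counts would keep the shares within 1.2 times and is argued against as the whole cause by the same value. These genes were picked for a low untreated level, which favours rises over falls, and on day 7 other positions gave 13.0%, so the rises in other positions stay open. Whether reads from unspliced RNA were counted more at 4 h was not tested.

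Peroxide cultures held 6.06 and 3.94 times the CPM of the 6 cycling genes of nutlin-3a cultures of the same library. A low level in every cell is argued against by the spread over peroxide-treated cells. Those with at least 3 of these UMIs were at least 34.2 times as many as a Poisson spread would give at 1000 UMIs per cell, and at least 8.97 times at 2000. Unthinned the ratio was 5.46 and 5.53 against 14.8 and 14.2 after nutlin-3a, there from 1 and 2 cells, so it does not set the treatments apart. Free RNA and doublets with untreated cells would, after the first round, keep an untreated well's barcode, so these counts cannot test them. At 1000 UMIs 41 of 2050 and 14 of 2125 peroxide-treated cells had at least 3 of these UMIs. After nutlin-3a 0 of 2548 and 0 of 2409 did. The lower 95% limit after peroxide was at least 2.36 times the upper one after nutlin-3a. Unthinned, 62 and 22 had so many against 1 and 2. A small group of peroxide-treated cells that still cycled may explain the difference from nutlin-3a, as a hypothesis. Untreated cells mixed into peroxide wells were not tested for and stay open beside it.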
